A study of Mus musculus with 6 samples.

How the data were processed

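RNA-seq libraries came from CD8+ T cells of C57BL/6 mice, 3 cultured with NaCl as the control and 3 with 5 mM itaconate, all for 48 h. Per the labels, total RNA was isolated with a column kit and libraries were made with a standard Illumina protocol. The authors deposited 1 gene-level table per library, with the column names of RSEM, a program that divides reads shared between genes and isoforms by estimated abundance. Expected counts, per the file headers, are the authors' estimates of reads or fragments per gene, not normalised. TPM values, per the file headers, were made by the authors by dividing by effective length and scaling each library to the same total. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8 and mm10, without saying which step used which. The RSEM version, the annotation release, the strand setting and any read trimming are not given in the sources used here. Levels of genes that overlap a gene on the other strand, and of genes with close paralogs or processed pseudogenes, depend on these settings.

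Each table listed 55487 genes, of which 99.83% had an Ensembl identifier in the GENCODE M21 annotation of the mouse genome GRCm38. That annotation was used for chromosomes, positions and gene classes only. Gene GC content came from the same reference. Between 5.99% and 6.93% of genes per library held an expected count further than 0.001 from a whole number, and all expected counts were rounded to whole numbers before testing. Totals per library lay between 18280217 and 31643408. Levels are counts scaled to library size (CPM) with edgeR's TMM factors, which lay between 0.9866 and 1.017, and are given as mean ± SD of 3 libraries.

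Itaconate was compared with control in all 6 libraries with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (two-sided, robust prior), after edgeR's expression filter with a minimum count of 10 and a minimum total of 15, which kept 12350 genes. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over these genes. Log2 fold changes are fitted values of itaconate relative to control with their standard errors. Adjusted p-values of single genes come from this test unless another is named. Before the data were examined, 46 gene lists were written from general knowledge of CD8 T cells, metabolism and itaconate, including markers of other cells. The 42 lists with at least 5 tested members were tested against all other genes with camera of limma 3.58.1, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over lists. Camera with a correlation estimated from the data, and the directional fry test, were run as alternatives. Fry asks whether the genes of a list move 1 way on balance, and does not compare them with other genes. Counts described as adjusted over the list alone repeat the adjustment within the members of 1 list.

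The genes named were set by a rule written before the data were examined. It takes the 10 largest increases and the 10 largest decreases among changed genes with a mean of at least 10 CPM, a gene symbol that is not a predicted name, and no overlap between the groups. It adds from each list described up to 2 risers and 2 fallers with the smallest adjusted p, and 17 genes fixed by name. Gapdh, Ldha, Isg15, Cd4 and Trdc in the report, and further genes in the closing observations, were chosen after their values were seen. Some genes that the rule takes are not reported here.

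Shares of counts per library were compared with a two-sided exact permutation test. Total counts (p 0.2), genes with a count above 0 (0.1), the share of the 10 most abundant genes (0.4), the mitochondrial share (0.7), the histone share (0.1), the protein-coding share (0.6), the pseudogene share (0.6) and the difference between gene length and effective length (0.9) were tested, and 0.1 is the smallest p that 3 against 3 libraries can give. That difference, which RSEM derives from fragment lengths, was 258.64 bases in control replicate 1 and between 229.22 and 239.07 in the other libraries. The 10 most abundant genes took 6.04% ± 0.185 of counts in control and 6.23% ± 0.0189 in itaconate libraries (SD, n = 3). Chi-square values per gene between libraries of 1 group, from 5.094 to 18.01 after scaling to depth, were checked, and no pair of libraries looked like a resequenced copy, which would give a value near 1.

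The gene test and the list test were tried on simulated counts with the common dispersion of the real libraries, 0.0052, for every gene. In them 200 of 12368 genes, and besides them the members of a planted gene list, were changed. Of the 200, with 50 planted at each size, the gene test recovered 42% of genes changed 1.25-fold and 68% of those changed 1.5-fold. It recovered 94% of those changed 2-fold and 98% of those changed 4-fold. Of its 178 calls, which include those on list members, 8 fell on unchanged genes (4.49%). The planted list was called and 0 other lists were. Differences near 1.25-fold can therefore be missed at this depth and replication. Simulated genes varied independently, whereas the estimated correlation within the ribosomal protein list was 0.847. The simulation cannot test list calls at the preset correlation, and its rates hold for 1 dispersion shared by all genes.

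Alternatives, fixed before the data were examined, were DESeq2 size factors, library sizes alone and upper-quartile factors for scaling, an offset for effective length, no filter on low counts, a filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), edgeR without its robust prior, the replicate number as a block, each library left out in turn, and an adjusted p under 0.01. Splits of the 6 libraries, matched random lists and removal of a loess trend of fold change on effective length and GC content (span 0.5), with 100 draws from the fitted trend with residuals shuffled among genes of like CPM, were computed for the closing observations. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, library tests and plots.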

Results

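Gene expression was measured by RNA-seq in CD8+ T cells, the lymphocytes that kill infected and tumour cells, from mice of the C57BL/6 strain. The cells had been kept for 48 h with 5 mM itaconate, a dicarboxylic acid that activated macrophages make from cis-aconitate, or with NaCl as the control. Each group held 3 libraries. The authors' expected counts summed to 26505318, 20469874 and 31643408 in control replicates 1, 2 and 3, and to 20216761, 18280217 and 23609543 in itaconate replicates 1, 2 and 3. Nothing in the labels says whether replicates came from separate mice or cultures, so p-values measure the spread between these libraries, which may be technical. The design implies a single comparison, itaconate against NaCl, which asks how itaconate changes gene expression in these cells. Acod1, which encodes the enzyme that makes itaconate, had rounded expected counts of 10, 3 and 9 in the control libraries and 3, 1 and 4 in the itaconate libraries, too few to be tested.

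With a preset correlation between genes, lists of genes induced by hypoxia-inducible factor 1 (HIF-1), of glycolysis genes and of interferon-stimulated genes were called lower in itaconate-treated cells, and genes activated by the oxidative-stress factor NRF2 were called higher. With a correlation estimated from the data none of these lists was called (adjusted p = 0.436 for each). Slc2a3, a glucose transporter, fell from 163 ± 7.0 CPM (normalised counts scaled to library size; mean ± SD, n = 3) to 74.3 ± 14 CPM, and Gbp5, an interferon-induced GTPase, fell from 117 ± 14 to 59.1 ± 5.5 CPM. Lgals3, which encodes the lectin galectin-3, rose from 5.59 ± 0.73 to 19.1 ± 3.4 CPM, and Itgae, the integrin chain CD103 of tissue-resident T cells, rose from 1.37 ± 0.52 to 11.1 ± 1.3 CPM. The mRNA of interferon-gamma did not differ detectably, at 455 ± 73 CPM in control and 468 ± 54 CPM in itaconate cells.

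Of 12350 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1487 changed at an adjusted p under 0.05, of which 825 were higher and 662 lower with itaconate. Most changes were small. The median absolute log2 fold change of the changed genes was 0.33, a 1.26-fold difference, and 128 genes changed at least 2-fold, 73 upward and 55 downward. The CPM of the groups did not overlap for 1478 of the 1487 genes, and did not overlap for 31.19% of all tested genes, where chance gives 10%. The count of changed genes fell to 726 without control replicate 2, to 896 without itaconate replicate 2 and to 835 without itaconate replicate 3, and to 567 when changes in effective transcript length were modelled. On log2(TPM + 1) values limma called 308 genes, of which 39.6% were higher, against 55.5% of the 1487.

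The 10 largest increases among genes with a mean of at least 10 CPM were those of Lgals3 (log2 fold change 1.77 ± 0.14, SE), Atp2b4, Ubtd1, Pmepa1, Abi3, Nt5e, Cables1, Igfbp4, Rasgrp2 and Atp1b1 (0.96 ± 0.10), with edgeR adjusted p-values from 3.26e-06 to 0.000678. Among them, Pmepa1, a target and inhibitor of TGF-beta signalling, rose from 17.1 ± 1.6 to 39.8 ± 1.8 CPM, and Nt5e, the ectonucleotidase CD73 that makes adenosine, from 7.61 ± 0.75 to 16.6 ± 1.2 CPM. Atp2b4 and Atp1b1 encode a calcium pump of the plasma membrane and a subunit of the sodium-potassium pump. The 10 largest decreases were those of Selp (-1.22 ± 0.10), Slc2a3, Slamf6, Ciart, Gbp2, Gbp5, St6gal1, Hilpda, Cd81 and Nrn1 (-0.91 ± 0.16), with adjusted p-values from 7.2e-06 to 0.0447. Selp, the adhesion molecule P-selectin, fell from 19.4 ± 1.5 to 8.27 ± 0.43 CPM, and Slamf6, a receptor of the SLAM family, from 28.5 ± 5.1 to 13.2 ± 0.69 CPM. Hilpda, a hypoxia-inducible regulator of lipid droplets, fell from 27.7 ± 2.9 to 14.3 ± 1.9 CPM. Gbp2 lost its call without any 1 library other than control replicate 3 (adjusted p 0.0672 to 0.136), and Nrn1 without itaconate replicate 1 (0.0512) or 2 (0.0564). In the GRCm38 mouse genome (GENCODE M21, looked up by the gene identifiers in the files), Lgals3 (ENSMUSG00000050335) lies on chromosome 14 at 47367751 to 47386160, and Selp (ENSMUSG00000026580) on chromosome 1 at 164115264 to 164150026. Slc2a3 (ENSMUSG00000003153) lies on chromosome 6 at 122727809 to 122801640, and all 3 are protein-coding genes.

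**Figure D1:**
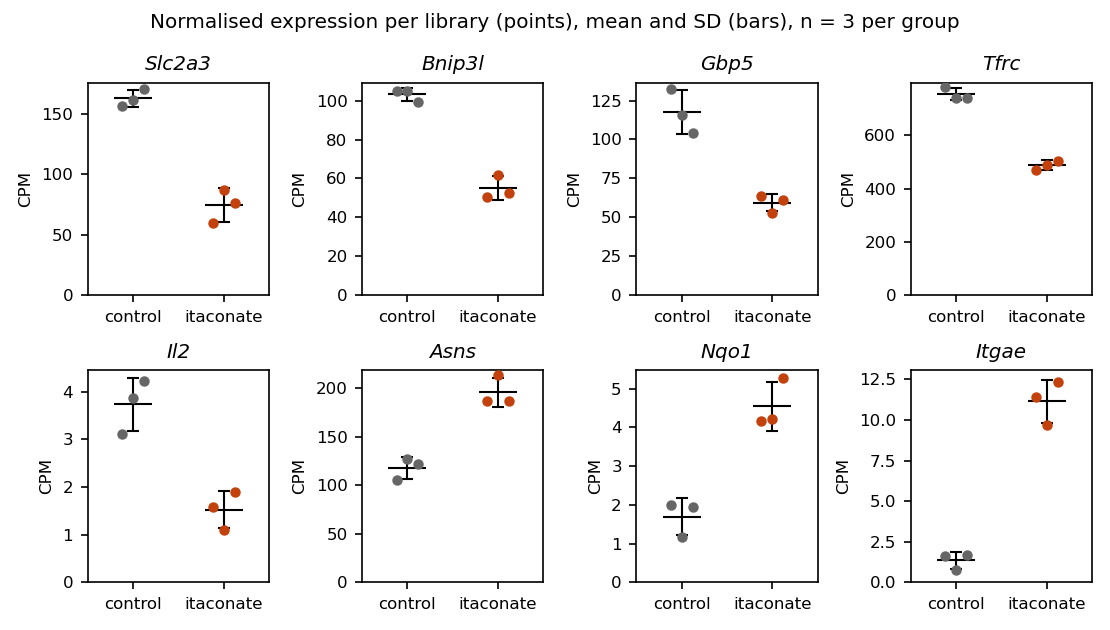
Normalised expression in CPM (vertical axes, each starting at 0) of 8 genes in the 3 control and 3 itaconate libraries. Points are libraries, horizontal marks are group means and error bars are SDs. Slc2a3, Bnip3l, Gbp5, Tfrc and Il2 were lower in every itaconate library than in every control library, and Asns, Nqo1 and Itgae were higher.

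**Figure D2:**
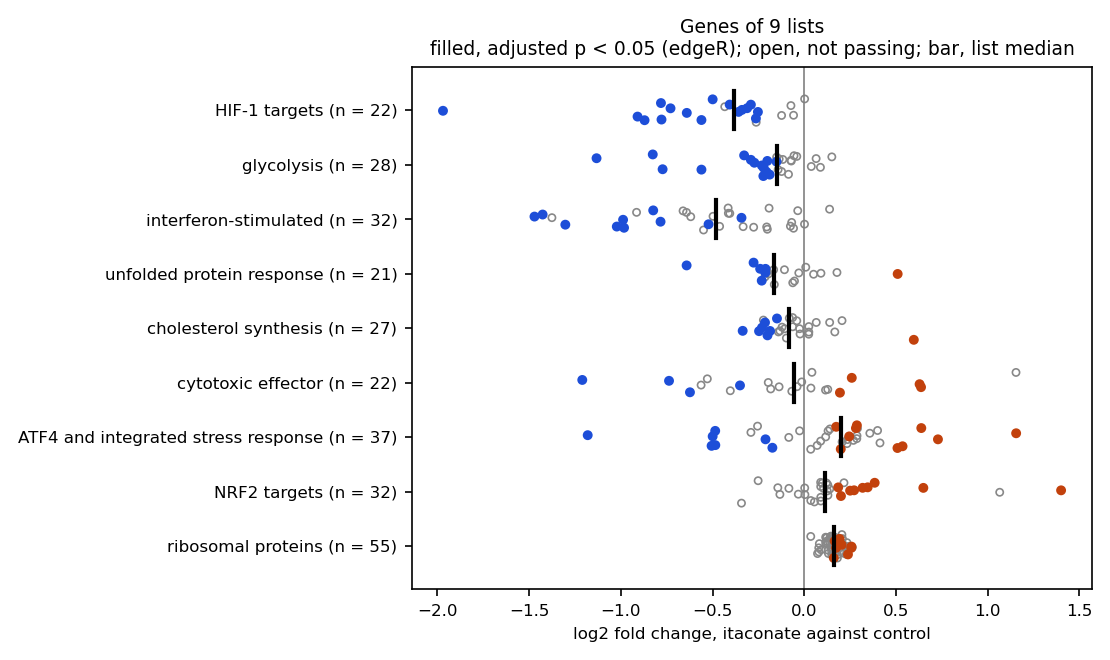
Log2 fold changes (horizontal axis, itaconate against control) of the tested genes of 9 lists, with the number tested after each name. Filled points passed an adjusted p of 0.05 in edgeR, open points did not, and black bars are list medians, which run from -0.48 for interferon-stimulated genes to 0.20 for genes of ATF4 and the integrated stress response. Vertical scatter within a list carries no information.

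HIF-1 target genes and glycolysis genes were called lower by limma's camera with a preset correlation of 0.01 (adjusted p 6.58e-16 and 1.07e-09), and 4 genes stand in both lists. Neither call held with an estimated correlation (adjusted p = 0.436 for each). Fry, which does not compare a list with other genes, called both lower (fry adjusted p 0.0339 for each). Of 22 tested HIF-1 targets, which cells switch on when oxygen is low or HIF-1 is stabilised, 16 fell, none rose and 6 did not pass (17 fell adjusted over the list alone), and the median log2 fold change was -0.38. Bnip3l, a mitophagy receptor, fell from 103 ± 3.3 to 55.0 ± 6.1 CPM (log2 fold change -0.91 ± 0.071, edgeR adjusted p 4.3e-06), and Ak4, a mitochondrial adenylate kinase, from 56.9 ± 0.99 to 31.1 ± 2.4 CPM (-0.87 ± 0.068, adjusted p 4.3e-06). Of 28 glycolysis genes, 14 fell, none rose and 14 did not pass (17 fell adjusted over the list alone), with a median of -0.15. Slc2a1, the glucose transporter GLUT1, fell from 169 ± 3.6 to 115 ± 12 CPM (-0.56 ± 0.068), and Slc16a3, the lactate exporter MCT4, from 150 ± 4.2 to 87.7 ± 12 CPM (-0.77 ± 0.086). Gapdh, the abundant glyceraldehyde-3-phosphate dehydrogenase, changed by -0.23 ± 0.044, and Ldha, lactate dehydrogenase, did not pass, at -0.12 ± 0.054 (adjusted p 0.16). Reads of Gapdh and other genes with many processed pseudogenes depend on how the authors' counting divided shared reads.

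Interferon-stimulated genes were called lower (camera adjusted p 8.45e-10), a call lost with an estimated correlation (adjusted p = 0.436) and with fry (adjusted p 0.0555). Of 32 tested members, 10 fell, none rose and 22 did not pass (11 fell adjusted over the list alone), with a median log2 fold change of -0.48. Relative to the control mean, the mean log2 CPM of the list was -0.792 and -0.736 in itaconate replicates 1 and 2 and -0.253 in itaconate replicate 3, and the median without 1 library ran from -0.65 to -0.34. Gbp5 changed by -0.99 ± 0.095 (edgeR adjusted p 0.00023), and Ifih1, the RNA sensor MDA5, fell from 10.4 ± 0.79 to 5.20 ± 1.1 CPM (adjusted p 0.000905). Isg15, a ubiquitin-like modifier, fell from 13.0 ± 2.4 to 4.77 ± 1.4 CPM (adjusted p 0.001).

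NRF2 target genes, which defend cells against oxidants and electrophiles, were called higher (camera adjusted p 0.00315). The call was lost with an estimated correlation (adjusted p = 0.436) and kept with fry (adjusted p 0.0379). Of 32 tested members, 9 rose, none fell and 23 did not pass (9 rose adjusted over the list alone), with a median log2 fold change of 0.11. Nqo1, a quinone reductase, rose from 1.70 ± 0.47 to 4.55 ± 0.63 CPM (1.40 ± 0.24, edgeR adjusted p 0.00174), and Ftl1, the ferritin light chain that stores iron, from 882 ± 58 to 1121 ± 35 CPM (0.35 ± 0.053, adjusted p 0.000859). Hmox1, heme oxygenase 1, and Slc7a11, the cystine transporter, which also respond to NRF2, did not pass, at 0.12 ± 0.12 (adjusted p 0.559) and 0.09 ± 0.17 (adjusted p 0.789). Tfrc, the transferrin receptor that imports iron, fell from 756 ± 24 to 489 ± 17 CPM (-0.63 ± 0.047, edgeR adjusted p 4.3e-06).

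The list of ATF4 targets and the integrated stress response, a programme that cells start when amino acids run short or proteins misfold, moved both ways: 10 of 37 tested members rose, 7 fell and 20 did not pass (15 rose and 8 fell adjusted over the list alone). The risers included Asns, asparagine synthetase, at 118 ± 11 CPM in control and 195 ± 15 CPM in itaconate cells (0.73 ± 0.075, edgeR adjusted p 0.000174), and Gpt2, a mitochondrial alanine transaminase (0.54 ± 0.057). The fallers included Ppp1r15a, a phosphatase subunit that ends the stress response (-0.51 ± 0.086), and Vldlr, a lipoprotein receptor (-1.18 ± 0.29), which lost its call without control replicate 1 (adjusted p 0.0549), control replicate 3 (0.0529), itaconate replicate 1 (0.0553) or itaconate replicate 3 (0.0739). Atf4 itself was at 614 ± 61 and 666 ± 38 CPM (adjusted p 0.327). The list, with a median of 0.20, was called higher (camera adjusted p 0.00653), but not without control replicate 1 (adjusted p 0.0771), with fry (0.175) or with an estimated correlation (adjusted p = 0.672).

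Lists of amino acid metabolism were not called by camera. Of 27 genes of aspartate, asparagine and glutamine metabolism, 5 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p 0.0508, past the threshold in 8 of 19 alternative analyses), and Ass1, argininosuccinate synthetase, rose from 97.9 ± 3.9 to 150 ± 3.5 CPM (edgeR adjusted p 4.69e-06). Of 29 genes of serine, glycine and one-carbon metabolism, 5 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p 0.187, fry adjusted p 0.0339). Phgdh, the entry enzyme of serine synthesis, rose from 766 ± 36 to 935 ± 23 CPM (0.29 ± 0.048), and Slc6a9, a glycine transporter, from 27.8 ± 3.0 to 39.5 ± 3.3 CPM (0.51 ± 0.088). Psat1, the next enzyme of that pathway, changed by 0.17 ± 0.046 (adjusted p 0.0248), a call lost without any 1 library other than control replicate 3 (adjusted p 0.0525 to 0.0868).

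Ribosomal protein genes were called higher as a list (camera adjusted p 4.36e-11), a call lost with an estimated correlation (adjusted p = 0.672) and with fry (0.199). Of 55 ribosomal protein genes, 9 rose, none fell and 46 did not pass (16 rose adjusted over the list alone), with a median log2 fold change of 0.16. Rps12, of the small ribosomal subunit, rose by 0.26 ± 0.054 on the log2 scale, a call that was lost without control replicate 2 (adjusted p 0.0568). Relative to the control mean, the mean log2 CPM of the list was -0.155, 0.0325 and 0.123 in control replicates 1, 2 and 3 and 0.0693, 0.263 and 0.171 in itaconate replicates 1, 2 and 3, so the groups overlapped. Its median was 0.08 without control replicate 1, and 0.05 once a trend of fold change with effective length and GC content was removed from all genes. Of 76 nuclear genes of oxidative phosphorylation, 1 rose, Sdhb, a subunit of succinate dehydrogenase, from 146 ± 1.8 to 174 ± 6.2 CPM (edgeR adjusted p 0.00339), and 75 did not pass (1 rose adjusted over the list alone). Their median of 0.10 gave a camera adjusted p of 0.000198, which was lost without control replicate 1 (median 0.03, adjusted p 0.343), with fry (0.378) and with an estimated correlation (adjusted p = 0.672). The library means of this list overlapped too, at -0.172 to 0.135 in control and 0.00254 to 0.178 in itaconate libraries. The median was 0.17 without control replicate 3, 0.15 without itaconate replicate 1, 0.06 without itaconate replicate 2, and -0.00058 once the trend with length and GC content was removed. Control replicate 1 also had the highest share of counts in mitochondrially encoded genes, 1.94%, against 1.252% to 1.554% in the other libraries. Of 31 genes of the tricarboxylic acid cycle, 5 rose and none fell (6 and 1 adjusted over the list alone; camera adjusted p 0.13, and 0.0457 without itaconate replicate 1).

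Lists of the unfolded protein response, cholesterol synthesis, S phase and p53 targets were called lower. With an estimated correlation none of these 4 lists was called (adjusted p = 0.436, and adjusted p = 0.443 for cholesterol synthesis), and with fry only the S phase list was (adjusted p 0.0379). Of 21 genes of the unfolded protein response, 6 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.17, camera adjusted p 0.00315). The faller with the smallest p was Atf6, a sensor of misfolded protein, from 41.7 ± 2.6 to 26.6 ± 2.3 CPM, followed by the chaperone Hspa5 (-0.28 ± 0.052), and the riser was Xbp1, a transcription factor of the same response, from 156 ± 4.7 to 222 ± 9.9 CPM (edgeR adjusted p 2.28e-05). Of 27 genes of cholesterol synthesis and its control, 7 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.08, and -0.05 without itaconate replicate 3; camera adjusted p 0.00575). Insig1, a sterol sensor partner (-0.34 ± 0.054), and the synthetic enzyme Cyp51 (-0.23 ± 0.045) fell, and Abcg1, which exports cholesterol, rose (0.60 ± 0.10). Of 47 genes of S phase and DNA replication, 5 fell, none rose and 42 did not pass (4 fell adjusted over the list alone; median -0.07, camera adjusted p 0.00809). Mcm3, a subunit of the replicative helicase, changed by -0.18 ± 0.044, a call lost without itaconate replicate 2 (adjusted p 0.0711) or 3 (0.0689). Of 22 p53 targets, 1 fell, Fas (-0.40 ± 0.12), and none fell adjusted over the list alone (median -0.14, camera adjusted p 0.00526). Fas lost its call without any 1 library other than control replicate 3 (adjusted p 0.0691 to 0.147). Of 40 mitosis genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p 0.29, fry adjusted p 0.042), and the proliferation marker Mki67 was at 514 ± 41 and 498 ± 68 CPM (edgeR adjusted p 0.831). Myc did not pass either, at 555 ± 30 and 570 ± 17 CPM (adjusted p 0.674).

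Genes of T cell function moved both ways. Of 22 tested genes of cytotoxic effector cells, 4 rose and 4 fell (4 and 9 adjusted over the list alone; camera adjusted p 0.187). Ctsw, a cathepsin of cytotoxic cells, rose from 46.3 ± 0.81 to 72.1 ± 1.3 CPM (edgeR adjusted p 9.31e-06), while Ccl5, a chemokine, fell from 9.05 ± 0.11 to 3.87 ± 1.1 CPM (adjusted p 0.000542) and Prdm1, the regulator BLIMP-1, from 13.5 ± 2.1 to 8.10 ± 1.4 CPM (adjusted p 0.00511). Fasl, the ligand of the death receptor Fas, rose by 0.63 ± 0.16 on the log2 scale, a call lost without control replicate 1 (adjusted p 0.0571), control replicate 2 (0.09), itaconate replicate 2 (0.0734) or itaconate replicate 3 (0.0851). Gzmb, the protease granzyme B, was at 4462 ± 347 CPM in control and 5107 ± 283 CPM in itaconate cells (0.19 ± 0.059, adjusted p 0.0485), with overlap between the groups. Its call was lost without control replicate 1 (adjusted p 0.151), control replicate 2 (0.186), itaconate replicate 2 (0.159) or itaconate replicate 3 (0.194). Prf1, the pore-forming protein perforin, was at 46.3 ± 5.6 and 35.0 ± 5.1 CPM (-0.40 ± 0.12), at the edge of the threshold with an adjusted p of 0.054, and it passed in 11 of 17 alternative analyses, among them those without control replicate 1 (0.0206) or itaconate replicate 3 (0.0185). The cytokine genes Ifng (adjusted p 0.898) and Tnf (42.4 ± 6.0 and 37.3 ± 4.5 CPM, adjusted p 0.366) did not pass, and Il2 fell from 3.74 ± 0.56 to 1.53 ± 0.39 CPM (-1.27 ± 0.25, adjusted p 0.00444).

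Of 25 activation genes, 4 rose and 6 fell (6 and 10 adjusted over the list alone). Besides Tfrc, the transcription factor Irf4 fell from 497 ± 12 to 399 ± 11 CPM (edgeR adjusted p 0.000496), while Irf8 rose from 615 ± 51 to 837 ± 43 CPM (adjusted p 0.000542). Egr3, which responds to the antigen receptor, rose by 0.30 ± 0.062 on the log2 scale, a call lost without control replicate 2 (adjusted p 0.0593). The list's camera adjusted p was 0.0497, and it was not called without control replicate 2 (0.1), control replicate 3 (0.0725), itaconate replicate 1 (0.0894) or itaconate replicate 3 (0.0644), nor with an estimated correlation (adjusted p = 0.443), fry (0.0633), DESeq2 size factors (0.052) or a filter of 50 counts (0.0594), 8 of 19 alternative analyses in all. Of 16 genes of inhibitory receptors and exhaustion, 4 rose and 3 fell (6 and 4 adjusted over the list alone; median -0.04, mean 0.12, camera adjusted p 0.938). Nt5e and Nr4a1 rose, the latter, an orphan nuclear receptor induced by antigen, from 222 ± 12 to 299 ± 25 CPM, and the inhibitory receptors Btla and Ctla4 fell, from 49.5 ± 4.5 to 35.1 ± 1.9 and from 425 ± 36 to 313 ± 27 CPM. Pdcd1, which encodes PD-1, was at -0.24 ± 0.081 and did not pass (adjusted p 0.0712), but did in 4 of 17 alternative analyses, among them that without itaconate replicate 2 (0.0396). Of 20 genes of naive and memory cells, 1 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p 0.379). The chemokine receptor Ccr7, which guides cells to lymph nodes, fell from 280 ± 15 to 222 ± 13 CPM. The riser, the cytokine receptor chain Il2rb (0.18 ± 0.053), lost its call without control replicate 2 (adjusted p 0.231), control replicate 3 (0.0764), itaconate replicate 1 (0.0885) or itaconate replicate 3 (0.197).

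Genes of homing and adhesion included the largest fold change of any list member that passed. Of 15 tested members, 6 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p 0.0765). The list was called higher in 6 of 19 alternative analyses, among them those without control replicate 1 (0.00783) or itaconate replicate 2 (0.0348), and its median of 0.16 turned below 0 without control replicate 2 (-0.02) or itaconate replicate 3. Itgae rose by 2.97 ± 0.22 on the log2 scale (edgeR adjusted p 4.3e-06), and Cxcr5, a chemokine receptor of B cell follicles, rose from 8.42 ± 0.24 to 15.3 ± 0.84 CPM. Itgb1, an integrin chain, fell from 218 ± 15 to 156 ± 8.3 CPM, and Cxcr4, another chemokine receptor, from 6.85 ± 0.62 to 3.17 ± 0.86 CPM. The regulatory T cell factor Foxp3 rose from 1.87 ± 0.63 to 12.4 ± 2.3 CPM (2.72 ± 0.22, adjusted p 1.1e-05). In GRCm38, Itgae (ENSMUSG00000005947) lies on chromosome 11 at 73090583 to 73147446 and Foxp3 (ENSMUSG00000039521) on chromosome X at 7573644 to 7595245, and both are protein-coding.

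Markers of the cells studied and of other cells were measured beside these lists. Of 16 genes of CD8 T cell identity, 2 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p 0.54). Cd8a rose from 497 ± 27 to 645 ± 14 CPM (edgeR adjusted p 0.000297), Cd5, a brake on antigen receptor signals, fell from 143 ± 13 to 110 ± 6.9 CPM, and Lat, an adaptor of that receptor, rose by 0.22 ± 0.050 on the log2 scale, a call lost without control replicate 2 (adjusted p 0.0844). Of 8 tested markers of CD4 T cells, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p 0.508, fry adjusted p 0.0379). Besides Foxp3, the folate receptor Izumo1r rose from 28.9 ± 4.2 to 49.8 ± 4.6 CPM, and Tnfsf8 and Ctla4 fell, while Cd4 was at 3.22 ± 1.3 and 3.72 ± 1.9 CPM (adjusted p 0.809). Of 5 markers of gamma-delta and innate-like T cells, Tcrg-C2 rose from 0.757 ± 0.18 to 2.87 ± 0.60 CPM (adjusted p 0.000962). Trdc, the delta-chain constant gene, did not pass, at 1.38 ± 0.15 CPM in control and 1.52 ± 0.12 CPM in itaconate libraries (adjusted p 0.822). Adjusted over the list alone, 3 of the 5 rose (camera adjusted p 0.0724). The list passed the threshold in 4 of 18 alternative analyses, among them that without itaconate replicate 2 (0.0438). No tested marker of B cells (10 tested), dendritic cells (8), macrophages (4), red cells and platelets (4), stroma and endothelium (2) or granulocytes (1) passed over all genes, while adjusted over the list alone 1 rose and 1 fell of the stroma and endothelium list. The most abundant of these markers were Ighm at 270 ± 11 and 294 ± 15 CPM (adjusted p 0.128) and Cd74 at 48.7 ± 8.3 and 46.2 ± 20 CPM (adjusted p 0.934). Of 5 tested markers of NK cells, 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p 0.665). Klrk1 changed by -0.29 ± 0.066 on the log2 scale (adjusted p 0.0113), a call lost without control replicate 2 (0.0515), itaconate replicate 2 (0.0593) or itaconate replicate 3 (0.0522). Eomes rose by 0.26 ± 0.076 (adjusted p 0.0477), a call lost without control replicate 1 (0.0925), control replicate 2 (0.184), control replicate 3 (0.0668), itaconate replicate 1 (0.109) or itaconate replicate 3 (0.171). The share of counts in mitochondrially encoded genes was 1.56% ± 0.35 in control and 1.43% ± 0.11 in itaconate libraries (SD, n = 3; two-sided exact permutation p 0.7, where the smallest possible is 0.1).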

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

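All alternatives were planned before the data were examined, and "changed" means an adjusted p under 0.05 in the test named. Of 3744 comparisons of 221 named genes with an alternative, 3362 kept their side of the threshold, 331 lost their call and 51 gained one. Among these named genes 0 called values changed direction. Of all 1487 changed genes, 9 had the opposite sign with effective length modelled, and 9 with limma-trend on log2(TPM + 1). Of 172 named genes that changed, 122 kept their call without each library in turn and 50 lost it without at least 1. For genes that changed, lost calls are named in the text only where 1 library was left out. Some of these genes also lost their call in other settings, such as Ak4 and Abcg1 in 2 each. Of values that did not pass, 14 genes and 15 lists changed sign in 54 comparisons each, and the 54 of genes are among the 3362. Against 1487 changed genes (825 higher, 662 lower, 128 at least 2-fold), modelling effective length gave 567 (325 higher, 242 lower), and limma-trend on log2(TPM + 1) gave 308 (122 higher, 186 lower, 38 at least 2-fold), and the cause was not tested. A filter of 50 counts, which removes low genes, left 66 changed at least 2-fold, and an adjusted p under 0.01 left 614 changed. With a replicate block 2419 genes changed (1315 higher, 1104 lower). Libraries of the same number deviated from their group means with correlations of 0.113, 0.0305 and 0.00337. Those of unlike numbers gave -0.093 to 0.0664. Such small values neither show nor exclude pairing by number, which the labels do not give. Leaving out 1 library gave 726 to 1400 changed genes, 407 to 707 higher, 319 to 693 lower, 96 to 129 at least 2-fold, and 12 to 16 called lists against 12. With an estimated correlation camera called 0 lists (2 at an unadjusted p under 0.05) and fry called 11. Dendritic cell markers, not called with all libraries (median log2 fold change 0.22, with a downward camera test, adjusted p 0.804), were lower without itaconate replicate 3 (-0.49, adjusted p 0.0192), and their median was 0.58 without itaconate replicate 2. At this depth genes with a few counts per library, such as Acod1, could not be tested.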

Other observations

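Further genes and lists changed that the report does not describe, and the genes named here, other than Bcl2l11 and mt-Co2, were chosen after their values were seen. Txnip, a brake on glucose uptake that cells induce with glucose, fell from 85.4 ± 2.7 to 45.7 ± 2.6 CPM (edgeR adjusted p 3.26e-06). The related arrestin Arrdc3 changed by -0.79 ± 0.11 on the log2 scale (adjusted p 0.000577). The iron-storing ferritin heavy chain Fth1 rose from 270 ± 6.6 to 306 ± 13 CPM (adjusted p 0.0197), a call of Fth1 lost without control replicate 2 (0.109), control replicate 3 (0.0631) or itaconate replicate 3 (0.115). Of 20 NF-kB targets, 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p 0.133, and 0.0314 without control replicate 1). Bcl2l11, the death-promoting protein BIM, fell from 34.0 ± 3.2 to 21.8 ± 1.8 CPM (adjusted p 0.000457).

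The cytoskeletal genes Vim and Capg rose, from 416 ± 29 to 668 ± 23 CPM and from 65.2 ± 2.6 to 107 ± 4.1 CPM (edgeR adjusted p 4.3e-06 for each). Of the 16 genes of inhibitory receptors and exhaustion, Havcr2, which encodes TIM-3, was at 1.54 ± 0.65 and 2.90 ± 0.77 CPM and did not pass (adjusted p 0.0752), but did in 3 of 16 alternative analyses, among them that without control replicate 3 (0.0212). Among 13 mitochondrially encoded genes, mt-Co2 fell from 354 to 247 CPM (adjusted p 0.000554), and the list was not called (median -0.26, camera adjusted p 0.0508; 1 rose and 3 fell adjusted over the list alone), but was in 6 of 19 alternative analyses, among them those without control replicate 2 (0.000206) or itaconate replicate 1 (0.0457). Hif1a, the regulated subunit of HIF-1, was at 328 ± 8.2 and 315 ± 13 CPM (adjusted p 0.468), and Nfe2l2, which encodes NRF2, at 50.2 ± 0.69 and 50.3 ± 3.9 CPM (adjusted p 0.983).

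Of the tests below, those on Cd4, on Foxp3 counts, on TGF-beta pathway genes, on HIF-1 targets outside glycolysis and on draws from a fitted trend were chosen only after the result was seen. The other splits of the 6 libraries put control and itaconate libraries in both groups, so differences between treatments add to the spread within groups. Their counts therefore do not measure calls by chance. The real split gave 1487 genes in edgeR, and the highest other gave 0 (142 to 1060 genes at an unadjusted p under 0.05, against 3271). In limma-voom the highest other gave 1, against 1292. Of 10 splits 1, the real one, gave as many, and 10 splits are too few for a share under 0.05.

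Foxp3 rose with itaconate together with Itgae and Ccr8 (0.936 ± 0.24 to 3.85 ± 0.98 CPM), genes that regulatory T cells express. An admixture of CD4 regulatory T cells would bring Cd4. Its log2 fold change was 0.21 ± 0.42 (edgeR adjusted p 0.809), against 2.72 ± 0.22 for Foxp3. Without itaconate replicate 3 that of Cd4 was -0.27, and without control replicate 3 it was 0.59. The folds start from unlike control levels, 3.22 ± 1.3 CPM for Cd4 and 1.87 ± 0.63 CPM for Foxp3. On the CPM scale Foxp3 gained 10.5 and Cd4 0.497, which argues against an admixture. Zbtb7b, a marker of CD4 T cells in general, did not pass (0.35 ± 0.18, adjusted p 0.248; 0.21 to 0.52 without 1 library). Cd40lg did not pass either (-0.31 ± 0.43, adjusted p 0.708; -0.81 to -0.07 without 1 library). It is not a marker of regulatory T cells and decides nothing here. Of markers of regulatory T cells, Il2ra (adjusted p 0.998) and Tnfrsf18 (adjusted p 0.379) did not pass, and Ctla4 fell (-0.44 ± 0.072). These 3 were too abundant in control (961, 144 and 425 CPM) for a small admixture to show. Gpr83 (1.41 ± 0.27, adjusted p 0.00393) and Izumo1r (0.79 ± 0.10, adjusted p 0.000924) rose as an admixture would predict. Ikzf2 did not pass (0.47 ± 0.15, adjusted p 0.0613) but did in 3 of 17 alternative analyses, among them that without itaconate replicate 3 (0.0464). Summed Foxp3 counts (148 and 762, rate ratio 6.518, lower 95% limit 5.459 for counting error only) decide nothing, because Foxp3 was chosen for its rise. A hypothesis is that TGF-beta signalling, which induces Foxp3, Itgae and Pmepa1, may be stronger: the median of 13 tested pathway genes, 0.23, lies at percentile 99.96 of random lists matched on mean CPM, which stays open, because the values of 10 of the 13 had been seen when the list was written, and the median of the other 3 lies at percentile 90.24.

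The fall of HIF-1 targets and glycolysis genes was set against a trend of fold change with GC content and length, and against a change of glycolysis alone. With the trend removed, the median log2 fold change of HIF-1 targets was -0.412 ± 0.0948 (bootstrap SE), against -0.3825 ± 0.0882 before. That of glycolysis genes was -0.2012 ± 0.0394, against -0.1508 ± 0.0313. Bootstrap SEs, here and in the next paragraph, resample the genes of a list as if independent, not the libraries. They leave out correlation between genes, estimated at 0.422 for HIF-1 targets and 0.204 for glycolysis genes, and can understate the error. HIF-1 targets were near all tested genes in median effective length (2505 against 2118 bases) and GC content (49.88% against 49.53%). The trend thus had little to remove from their median. The 18 HIF-1 targets outside the glycolysis list had a median of -0.4202 ± 0.115. As 16 of 22 HIF-1 targets fell and 4 genes stand in both lists, a negative median was certain beforehand. It shows only that the fall was not confined to glycolysis genes. A hypothesis left open is that itaconate may lower HIF-1 activity, although Hif1a mRNA differed by less than the test could call, and protein levels were not analysed here.

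Ribosomal protein genes and nuclear genes of oxidative phosphorylation are short, with median effective lengths of 489.5 and 460.6 bases against 2118 for all tested genes, and short genes could move with RNA or fragment length. The 175 named ribosomal protein pseudogenes held 1020.5 CPM in control and 1028.4 CPM in itaconate libraries, against 75967 and 84429 CPM for the genes. So small a share could hardly change the log2 ratio of summed CPM, which was 0.1506 with them and 0.1524 without. A shift of reads from these 175 does not account for the ribosomal median of 0.16, and pseudogenes under other names were not tested. That median lay at percentile 100 of random lists matched on length, GC content and CPM, and 0.04607 ± 0.0107 was left with the trend removed, which meets the bound set before the result was seen, but the bound was too weak: the matched genes were longer (664 against 490 bases) and less abundant (405 against 1270 CPM), and 42 of 100 draws from the fitted trend alone passed the percentile bound of that test. The real median and remainder lay above the highest of these draws (0.1557 and 0.0414), which move genes independently although the estimated correlation within the list is 0.847, so a trend stays open. For oxidative phosphorylation the percentile was 99.29 and the corrected median -0.00058 ± 0.00777, so for both lists, with medians of 0.08 and 0.03 without control replicate 1, a length trend and a change of these genes cannot be told apart.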
